A study of Rattus norvegicus with 16 samples.

How the data were processed

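Total RNA from hippocampus and frontal cortex of male LOU/C/Jall rats was labelled with Cy3 and hybridised by the authors to one-colour Agilent rat arrays, 1 per sample. Per the labels, the rats were decapitated under isoflurane and the regions dissected and frozen before extraction. The labels give 4 groups of 4 arrays: young and old hippocampus, and young and old frontal cortex. They give 5 months as the young age and the series design text gives 3, and which holds is not known. Title letter codes name the arrays here and were not used to pair them in the main fits.

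The values used are log2 signals as deposited in the series value table, 1 column per sample, joined to the labels by sample identifier. The authors quantified the scans with Agilent Feature Extraction per the labels, which give no version. The background correction, the normalization and the offset are not given in the sources used here. The scale was read as log2 from the range of 4.94 to 17.8, and every column has the same quartiles, with a median of 6.77 and an upper quartile of 9.17, as quantile normalization would leave them. The design written before the data were examined assumed the raw signal table. Its 16 columns match no sample by name, so it was not used except for spot names, and slides could not be compared. Signals are relative, and for arrays only their number limits the precision stated here. Negative control spots averaged 4.99 log2 (308 spots), dark corners 5.03 (35 spots) and bright corners 12.8 (14 spots) on this scale.

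Of 62976 spots, 45904 were probes with a listed gene. Symbols of 39826 probes were updated by accession from a RefSeq table of the GRCr8 assembly and 6078 kept the array's symbol. The other 17072 spots, controls among them, have no listed gene and were left out of the comparisons. Each array was shifted by its 75th percentile over gene probes, which lay between 9.42 and 9.44. A gene was represented by its probe of highest mean signal over the 16 arrays. It was kept when its highest group mean exceeded the 40th percentile of the probe means, 6.49 on the deposited scale. This left 10056 of 16974 genes, of which 8456 have more than 1 kept probe.

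R 4.3.3 with limma 3.58.1 fitted the 4 group means to all 16 arrays (12 residual and 4.07 prior degrees of freedom). Moderated two-sided p-values were adjusted by Benjamini-Hochberg over the kept genes for each of 4 comparisons: age in hippocampus, age in frontal cortex, the difference of those age effects, and region over both ages. A gene is called at an adjusted p under 0.05. Differences are old minus young, or hippocampus minus frontal cortex, with the moderated SE. The 40 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. In hippocampus fry gave an adjusted p of 0.00248 for the complement and microglia list. In frontal cortex its smallest adjusted p was 0.476. The comparisons, the lists, the alternatives other than those stated as added, and the rule for naming genes were fixed before the data were examined.

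For each age comparison the text names the 10 largest rises and the 10 largest falls among called genes with a symbol whose old and young arrays do not overlap. With fewer than 5 called genes it names the 10 smallest p in each direction instead. It also names up to 4 members with the smallest p of each list that passes, a set of genes fixed in advance (C3, Gfap, Cd74, Arc, Fos, Egr1, Bdnf, Dcx, Mbp, Igf1, App and Apoe), the 10 smallest p of the difference of age effects, and the 5 largest region differences each way with up to 4 members of the lists that mark a region. Other names, such as St8sia5 in frontal cortex, were chosen after their values were seen.

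The procedure was tested on simulated data with 100 changed genes per effect size among 10056. In hippocampus 54% of changes of 0.5 log2 and 93% of changes of 1 log2 were called, with 7 false calls among 154. In frontal cortex these were 63% and 96%, with 4 false calls among 163. A simulated shift of 0.3 log2 in 1 list, complement and microglia, was called in both regions with 0 other lists. The simulated noise was independent between genes, while the estimated correlation of this list in the real arrays was 0.21. The simulation therefore does not show how often camera at the preset correlation calls lists falsely when their genes vary together. The false gene calls carry the same limit. Many changed genes also ease the Benjamini-Hochberg adjustment, so the shares called may be too high for data with few calls, as in hippocampus.

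The alternatives were quantile normalization, a median shift, the values as deposited, no filter and a stricter filter on dim probes, the mean of all probes of a gene, a variance trend with robust settings, array weights, the 8 arrays of a region alone, a replicate block by title code, a fold minimum, camera with an estimated correlation or on ranks, a covariate for dissection markers, and leaving out each array in turn. Single marker lists as covariates, leaving out the codes AF and AG, age averaged over both regions, and the lists over both regions with an estimated correlation were added after the data had been seen.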

Results

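Messenger RNA levels were measured on one-colour Agilent rat arrays in brain tissue of male rats of the inbred LOU/C/Jall strain. The 16 arrays fall into 4 groups of 4: hippocampus and frontal cortex, each from young and from old rats. The sample labels give the young rats as 5 months old and the series design text gives 3 months, while both give 26 months for the old rats. Each group holds 4 title letter codes, Y, Z, AA and AB for young and AF, AG, AH and AI for old, and each code occurs once per region. A code may stand for 1 animal, which the labels do not state, so the p-values below measure the spread between these arrays. The series title asks which genes go with ageing well. The arrays hold no other strain, so the comparisons are between ages and between regions within LOU/C/Jall.

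Of 16974 genes on the array, 10056 had a signal above the intensity minimum in at least 1 group and were tested. The number of arrays limits the precision: the median residual SD per gene was 0.165 log2. Arrays of 1 group correlated with a median r of 0.989 in young hippocampus, 0.983 in old hippocampus, 0.988 in young frontal cortex and 0.983 in old frontal cortex. The first principal component held 41.9% of the variance and the next 13.8%.

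Markers of tissue that borders the dissected regions, and of blood, varied between arrays of the same group. The choroid plexus list, which covers genes of the epithelium that secretes cerebrospinal fluid, averaged 2.48 log2 above its genes' means on young hippocampus array AB and 2.77 on old hippocampus array AI. On old hippocampus array AG the same mean was -0.67. Striatal markers averaged 1.73 on old frontal cortex array AG and -0.33 on young frontal cortex array Z. The pericyte, smooth muscle and meninges list averaged 0.96 on young frontal cortex array Z and 0.74 on array Y, and its group mean was 0.42 in young and -0.21 in old frontal cortex. Erythrocyte markers averaged 1.03 on old hippocampus array AF and 1.18 on old frontal cortex array AF. These list means are set beside the gene groups they move with.

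**Figure D1:**
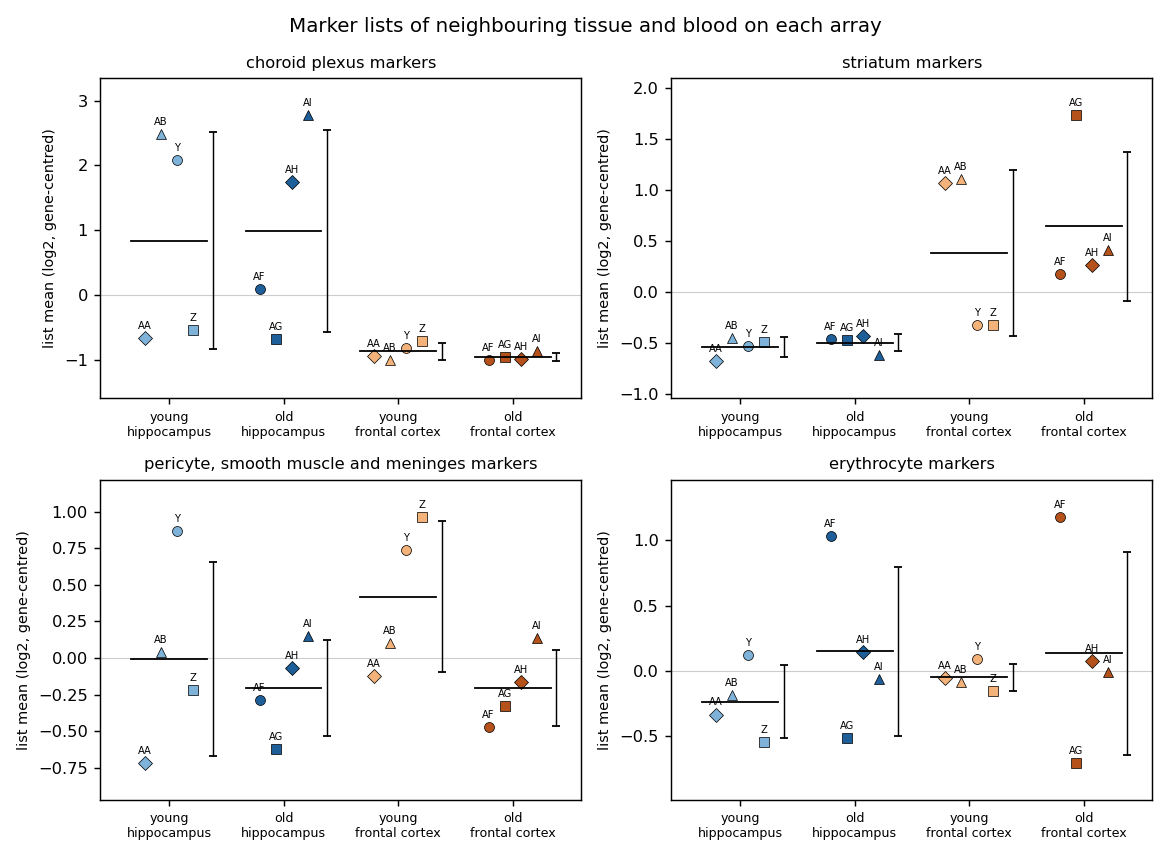
Mean of each marker list per array (log2, every gene centred on its mean over the 16 arrays) in the 4 groups. Points are arrays with their title codes, horizontal lines are group means and error bars are SD (n = 4); choroid plexus markers reach 2.77 on old hippocampus array AI, and erythrocyte markers are highest on both AF arrays.

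Old and young hippocampus were compared to find the genes that differ with age in this region. Complement C3, the central component of the complement cascade, was 1.5 ± 0.14 log2 higher in old hippocampus (SE, n = 4 per group), which is 2.83-fold. Its level was -0.38 ± 0.14 (SD, n = 4) in young and 1.12 ± 0.32 in old hippocampus, relative to the 75th percentile of each array. The calcium-binding protein S100a4 was higher by 1.05 ± 0.15 log2, the leukocyte actin-binding protein Lsp1 by 0.84 ± 0.12, and Gpnmb, a transmembrane glycoprotein of phagocytes, by 0.76 ± 0.11. In each of these genes all 4 old arrays lay above all 4 young arrays. The adjusted p was 0.000155 for C3 and 0.0123 for the other 3 genes.

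These 4 genes were the only ones called in hippocampus by limma at an adjusted p under 0.05, and 0 genes were called lower. With only the 8 hippocampus arrays C3 alone was called (adjusted p = 0.017), with array weights 8 genes were called, and without the codes AF and AG 20. At an unadjusted p under 0.05 there were 681 genes, 457 higher and 224 lower, where 502.8 are expected with no difference. C3 was called in each of the 16 fits that left out 1 array, S100a4 and Gpnmb in 12 and Lsp1 in 11. Without young hippocampus array AA, AB or Z, C3 alone was called, without old hippocampus array AH 2 genes, and without old hippocampus array AI or young hippocampus array Y 7.

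The genes next in order of p did not pass the threshold. Higher were Tyrobp (0.57 ± 0.10 log2) and Trem2 (0.55 ± 0.10), a microglial adaptor and its receptor, Aspg (0.62 ± 0.11) and the metallothionein Mt2A (1.2 ± 0.22), each at an adjusted p of 0.0702. The macrophage lysosomal protein Cd68 (0.73 ± 0.14) and Itgam (0.63 ± 0.12), the integrin known as CD11b, stood at 0.119. Lower were the ganglioside sialyltransferase St8sia5 (-0.51 ± 0.11, adjusted p = 0.188) and Dbndd1 (-0.36 ± 0.10, adjusted p = 0.451). Actr1b, Gprin1, Sar1a, Itm2a, Tmem74, Masp1, Spata2 and Zfp518a had differences between -0.24 (Spata2) and -0.68 (Itm2a), each at an adjusted p of 0.472. The 2 probes of Masp1 gave opposite signs, -0.47 and 0.35.

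Complement and phagocytic microglia genes were the group most clearly higher with age in hippocampus. Of 28 measured members, 27 had a positive difference, with a median of 0.40 log2. Over all genes 2 members were called higher, C3 and Gpnmb, and 18 were called higher adjusted over the list alone. The list passed limma's camera test at an adjusted p of 2.24e-23, and it was the only list to hold with an estimated correlation (adjusted p = 0.0287 with an estimated correlation). With the choroid plexus list mean as a covariate its median was 0.40, and with the erythrocyte list mean 0.40.

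Antigen presentation and interferon lists were also higher in old hippocampus in the camera test. All 17 measured members of the MHC class I and immunoproteasome list had positive differences (median 0.26, adjusted p = 1.03e-08), with RT1-A2 at 0.62 and Psme2 at 0.30. All 6 members of the MHC class II list did so too (median 0.51, adjusted p = 0.00275), led by Cd74, the invariant chain, at 1.43 ± 0.41 log2. The interferon response list had 20 of 24 members positive (adjusted p = 0.000124), with Ifi27 at 0.43 and Ifi27l2b at 0.41. These calls were lost with an estimated correlation, at an adjusted p of 0.323 for MHC class I, 0.422 for MHC class II and 0.451 for the interferon response. The MHC class II call was also lost without old hippocampus array AI (median 0.35, adjusted p = 0.0637), and the interferon median was 0.11 without that array. Array AI held the highest choroid plexus mean. The MHC class I median was 0.15 without young array AA. Adjusted over the list alone, 5 genes of MHC class I, 2 of MHC class II and 2 of the interferon list were called higher. MHC class I genes have near-identical copies, so their single values are uncertain.

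Further hippocampal lists passed camera as higher with age, and each was lost with an estimated correlation. Ribosomal protein genes, whose near-identical copies make single members uncertain, had 56 of 67 members positive (median 0.09, adjusted p = 1.59e-06, and adjusted p = 0.451 with an estimated correlation), with Rpsa at 0.46 on its brightest probe while its 3 probes differ in sign. The T cell, B cell and plasma cell list had 6 of 6 members positive (adjusted p = 0.0104, estimated 0.141). Only 6 of the 37 symbols fixed for it were kept, so its other markers were not tested. The smallest p was in the leukocyte genes Cd53 at 0.39 and Ptprc at 0.33. Cd52, at 0.57, had a larger but more variable difference and lay under the intensity minimum in both ages. Astrocyte genes had 16 of 20 positive (adjusted p = 0.0152, estimated 0.485), with the intermediate filament Gfap at 0.69 and Lcn2 at 0.85. The antioxidant and metal binding list had 30 of 43 positive (adjusted p = 0.0403, estimated 0.603), with Mt2A at 1.2 and the metallothionein Mt1 at 1.24. Erythrocyte genes had 10 of 10 positive (median 0.46, adjusted p = 0.0307, estimated 0.70), and the old array AF held the highest list mean, 1.03. Without AF the erythrocyte median was 0.076 (adjusted p = 0.666), and this call was also lost without young array AB or Z. The antioxidant call was lost without old array AH or AI or young array AA, AB or Z, and its median of 0.04 was 0.075 without old AG, 0.086 without young Y and 0.076 without young Z. The astrocyte call was lost without old AI or young AB. Globin genes, too, have near-identical copies.

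Lower in old hippocampus were 3 lists, again only at the preset correlation. Immediate-early genes, which neurons transcribe within minutes of activity, had 18 of 26 members negative (median -0.11, adjusted p = 0.0161, estimated 0.689), with Arc at -0.35 and Dusp1, under the intensity minimum in both ages, at -0.35. Synaptic vesicle and postsynaptic density genes had 27 of 40 negative (median -0.09, adjusted p = 0.0307, estimated 0.689), with Syn1 and the vesicular glutamate transporter Slc17a7 each at -0.26. The pericyte, smooth muscle and meninges list had 19 of 24 negative (median -0.22, adjusted p = 0.0307, estimated 0.865), with Vtn at -0.43 on its brighter probe and 0.039 on the other. Without young array Y, which stood apart in Vtn, the difference was -0.14. Each of these calls rests on single arrays. The synaptic median was 0.012 without old array AI and -0.058 without young AA, and the call was lost without these or young AB. Array AI held the highest choroid plexus mean, 2.77, and AB the next, 2.48. The immediate-early call was lost without old AH, old AI (median -0.063) or young AB. The meninges median was 0.091 without young array Y and -0.052 without old AG, where the call was lost, as it was without young AB, and -0.37 without old AI, -0.46 without young AA and -0.33 without young Z. In total 12 of the 40 lists passed in hippocampus, and without young hippocampus array AB 7 passed. With the stricter filter on dim probes 4 passed, all of them higher, so that none of the lower lists did.

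Old and young frontal cortex were compared in the same way. C3 and S100a4 were again higher, by 1.17 ± 0.14 log2 (2.24-fold, adjusted p = 0.00489) and 1.13 ± 0.15 log2 (2.19-fold, adjusted p = 0.00515). The protease inhibitor A2m was higher by 1.25 ± 0.22 (adjusted p = 0.0198) and Lsp1 by 0.66 ± 0.12 (adjusted p = 0.0237). Lower were Klhl14 at -1.60 ± 0.29 (adjusted p = 0.0198), the neuromedin B receptor Nmbr at -1.27 ± 0.18 (adjusted p = 0.00692), and Dusp1, a phosphatase of MAP kinases, at -0.74 ± 0.11 (adjusted p = 0.00692). In each of these genes the 4 old arrays were separated from the 4 young arrays.

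limma called 97 genes in frontal cortex, 56 higher and 41 lower. With only the 8 frontal cortex arrays it called 29, of which 18 are among the 97, and without the filter on dim probes 47, 34 higher and 13 lower. At an unadjusted p under 0.05 there were 2233, 1040 higher and 1193 lower. The old and young arrays did not overlap in 1287 genes, 12.8% of those tested, where chance gives 2.86%. In hippocampus the same count was 459, or 4.56%.

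**Figure D2:**
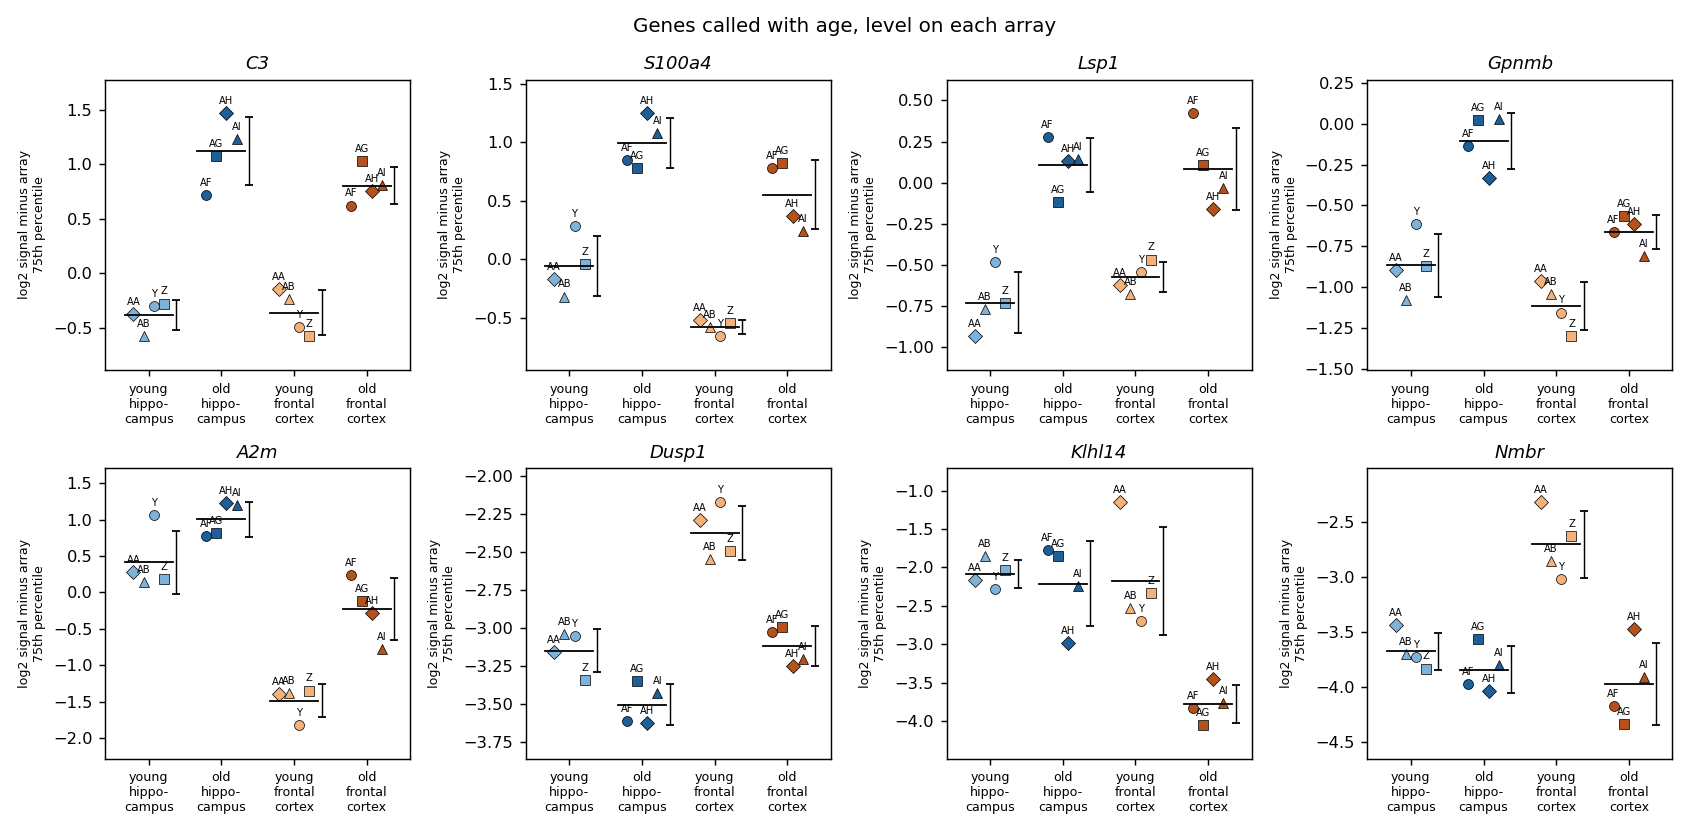
Level of 8 genes called with age on each array (log2 signal minus the array's 75th percentile) in the 4 groups. Points are arrays with their title codes, horizontal lines are group means and error bars are SD (n = 4); the old arrays lie above the young arrays for C3, S100a4 and Lsp1 in both regions, and below them for Klhl14, Nmbr and Dusp1 in frontal cortex.

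The other large rises in frontal cortex were Pbld1 (1.08), Ttc4 (1.01), Heatr8 (0.99), the apoptosis inhibitor Birc7 (0.91), Lipogenin (0.86), Slc26a10 (0.80) and Npff (0.80), the precursor of neuropeptide FF. The 2 probes of Ttc4 gave -0.38 and 1.01. The other large falls were the adaptor Sla (-1.20), Shisa3 (-1.11), the secreted Wnt inhibitor Frzb (-0.78), Tmem130 (-0.77), Clmp (-0.73), Rnf182 (-0.68) and Tspy26 (-0.65). Adjusted p for these genes ran from 0.0125 (Heatr8) to 0.0404 (Clmp). In old frontal cortex Klhl14, Nmbr, Sla, Shisa3, Clmp, Tspy26 and Dusp1 lay under the intensity minimum, where background makes up much of the signal. St8sia5, lower but not called in hippocampus, fell by 0.62 log2 here (adjusted p = 0.0198).

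The frontal cortex count rests on single arrays. It was 8 without old frontal cortex array AF, 19 without AG, 251 without AH and 739 without AI. It was 6 without young frontal cortex array AA, 14 without AB and 4 without Z. Leaving out a hippocampus array gave 59 genes for old AG, 59 for young AB and 56 for young Z. C3, S100a4, Dusp1 and Nmbr were called in all 16 of these fits. The 97 genes kept their sign in every fit, which their selection in the same arrays nearly fixed in advance. Without the codes AF and AG in both regions, chosen after their blood and striatal markers were seen, 2 genes were called.

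In frontal cortex immediate-early genes were lower and myelin genes higher by camera at the preset correlation, and neither call held otherwise (adjusted p = 0.956 with an estimated correlation for each). Immediate-early genes had 20 of 26 members negative (median -0.28, adjusted p = 0.00198). Dusp1 and Plk3 (-0.44, adjusted p = 0.0485) were called, and 6 members adjusted over the list alone. Plk3 was called in only 4 of the 16 fits that left out 1 array, and Dusp1 in all 16. Arc stood at -1.02 ± 0.24 (adjusted p = 0.0601) and Fos at -0.77 ± 0.21 (adjusted p = 0.0712). Myelin and mature oligodendrocyte genes had 25 of 28 positive (median 0.27, adjusted p = 0.00205), with Hapln2 at 0.88, Opalin at 0.72, Mag at 0.68 and Tspan2 at 0.68, and 4 were called adjusted over the list alone. On single arrays the myelin list was lowest on young frontal cortex arrays Z (-0.57) and Y (-0.55), which held the highest meninges means, and among old arrays highest on AG (0.41), which held the highest striatal mean. The myelin median was 0.12 without AG and 0.18 without Y, where the call was lost (adjusted p = 0.073 and 0.0529), and 0.17 without Z. The immediate-early median was -0.18 without old array AH, and the call was lost without old array AI (adjusted p = 0.0641). Complement and microglia genes had 20 of 28 positive (median 0.19, adjusted p = 0.00373, and adjusted p = 0.956 with an estimated correlation), a call lost without old array AH (adjusted p = 0.094), and adjusted over the list alone 3 were higher and 1, Spp1, was lower.

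The meningeal and matrix lists were lower in old frontal cortex at the preset correlation. The pericyte, smooth muscle and meninges list had 21 of 24 members negative (median -0.66, adjusted p = 0.00198), with the matrix proteoglycan Dcn at -1.13 and Bmp7 at -0.92, and 0 members were called. Collagen and extracellular matrix genes had 22 of 26 negative (median -0.24, adjusted p = 0.0214), with Loxl1 at -0.89 and, in the other direction, Col6a1 at 0.54. Oxidative phosphorylation genes had 47 of 64 negative (median -0.06, adjusted p = 0.0107). The complex I subunit Ndufs8 fell by 0.42 log2 (adjusted p = 0.0383), and was called in only 5 of the 16 fits that left out 1 array. The ATP synthase subunit Atp5f1b stood at -0.67, and 5 members were called lower adjusted over the list alone. Ribosomal protein genes had 50 of 67 positive (median 0.06, adjusted p = 0.0446), with Rpl4 at 0.33. The collagen call was lost without old array AF or young array Y or Z, and the ribosomal call without old array AH (median 0.035) or AI or young array AB, Y or Z. None of the 7 lists that passed in frontal cortex held with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each). Without young frontal cortex array Y 4 lists passed.

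**Figure D3:**
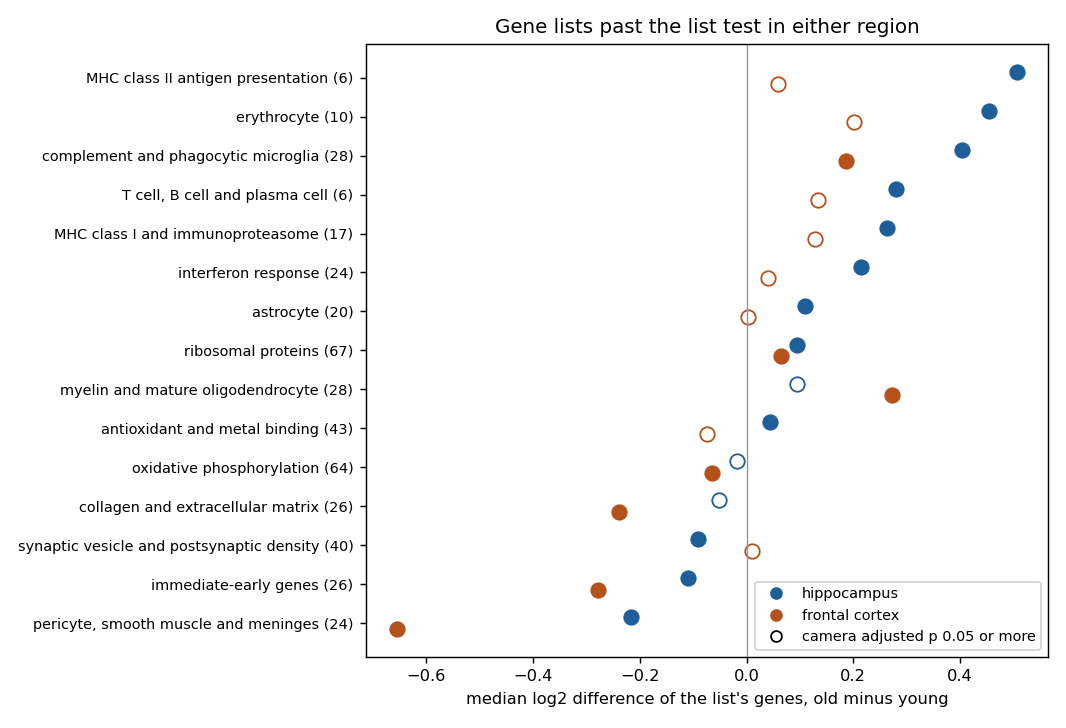
Median log2 difference, old minus young, of the measured members of each list that passed the list test in either region, with the number of members in parentheses. Blue marks hippocampus and orange frontal cortex, and open circles did not pass; complement and microglia genes stand at 0.40 in hippocampus and 0.19 in frontal cortex, and the meninges list at -0.66 in frontal cortex.

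No other list passed in either region. Closest were chaperones in frontal cortex (adjusted p = 0.0634) and the lysosome and autophagy list in hippocampus (adjusted p = 0.106). The glucocorticoid response list stood at 0.15 in hippocampus and 0.178 in frontal cortex, and the striatal list at 0.997 and 0.344. Choroid plexus markers (0.843 and 0.924) and endothelial genes (0.644 and 0.869) did not pass. Neither did neurogenesis and proliferation (0.597 and 0.340), senescence and inflammatory cytokines (0.298 and 0.965), insulin, IGF and longevity signalling (0.911 and 0.869), or amyloid and tau genes (0.783 and 0.701). The lists for oligodendrocyte precursors, glutamate receptors, GABAergic interneurons, GABA receptors, monoamine and acetylcholine receptors, calcium channels, the circadian clock, neurotrophic factors, cholesterol biosynthesis, epigenetic enzymes, ependyma, thalamus and septum, neocortex, hippocampal neurons and pituitary hormones had adjusted p between 0.13 and 0.965 in the 2 regions. In each list that passed, the median, the mean and the test had the same sign.

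Of the genes followed whatever their result, C3 alone passed with age. Gfap was higher in all 4 old arrays of each region, by 0.69 ± 0.18 log2 in hippocampus (adjusted p = 0.457) and 0.64 ± 0.18 in frontal cortex (adjusted p = 0.0808). Cd74, at 1.43 in hippocampus, stood at 0.36 in frontal cortex (adjusted p = 0.634), and Fos, at -0.77 in frontal cortex, stood at -0.26 in hippocampus. The neurotrophin Bdnf stood at -0.05 and -0.47, the immature-neuron gene Dcx at -0.08 and -0.25, and Egr1 at -0.29 and -0.15. Igf1 stood at -0.15 and -0.19, App at -0.04 and -0.08, Apoe at 0.02 and 0.02, and Mbp, the myelin basic protein, at -0.02 and 0.10. In hippocampus the probes of Bdnf, Apoe and Mbp differ in sign.

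Whether age acts differently in the 2 regions was tested by the interaction term. limma called 0 genes, and 266 had an unadjusted p under 0.05, where 502.8 are expected with no difference. Why the count lay below that number was not tested. The smallest p belonged to Sla, Spp1, Nmbr and Frzb, with hippocampal minus cortical age effects of 1.18, 1.60, 1.10 and 0.81 log2. Spp1, which encodes the secreted phosphoprotein osteopontin, had age effects of 0.70 in hippocampus and -0.90 in frontal cortex. Nvl (-0.54), Trhr2 (-0.62), Sycp2l (-0.80), Sfxn2 (-0.65), Lipogenin (-1.0) and Akirin2 (0.40) followed, and all stood at an adjusted p of 0.999. Sla, Spp1, Nmbr, Trhr2 and Sycp2l lay under the intensity minimum in young and old hippocampus, where background can mask an age effect. Without young frontal cortex array AA, 1 gene was called, Spp1. A gene called in 1 region and not in the other is therefore not shown to differ between them.

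The age effects of the regions had the same sign in 7164 of the 10056 genes, or 71.2%. C3, S100a4 and Lsp1 were called in both, where 0.0386 shared calls are expected of independent lists. The 2 comparisons are not independent, because both use the same estimate of spread for a gene. A gene of small spread is favoured in both, so chance can share more calls than this. Of the 97 genes called in frontal cortex, 91 had the same sign in hippocampus and 41 of them an unadjusted p under 0.05. Across the tested genes, which are not independent replicates, the 2 age effects correlated with a Pearson r of 0.565 and a Spearman rho of 0.597. With the regions' effects taken from different title codes, 2 per group, the median r over 36 arrangements was 0.339 (0.116 to 0.454), against 0.366 with the same codes at that size.

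**Figure D4:**
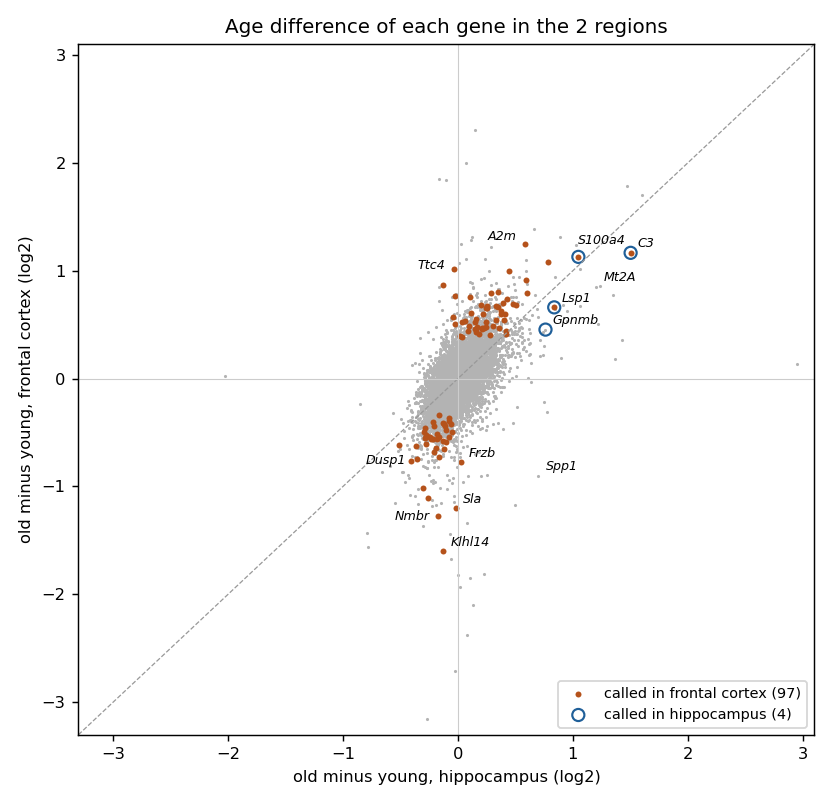
Age difference (old minus young, log2) of each of 10056 genes in hippocampus and in frontal cortex, with the line of equal differences dashed. Orange points were called in frontal cortex (97) and blue circles in hippocampus (4); C3, S100a4 and Lsp1 lie at the upper right, and Spp1 at the lower right.

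Hippocampus and frontal cortex were compared over both ages as a scale for the age effects and a check of the region labels. Among the genes with the largest differences, Klk8, a protease also called neuropsin, was higher in hippocampus by 4.77 ± 0.10 log2 (n = 8 per region). The transcription factor Nhlh1 was higher by 4.38 ± 0.13, the dentate granule cell gene C1ql2 by 4.27 ± 0.17 and Cabp7 by 3.81 ± 0.10. Ttr, the main secreted protein of choroid plexus, was higher by 4.65 ± 0.78. Cyp11b1 (-3.63 ± 0.12), Ucma (-3.27 ± 0.22), Cdhr1 (-2.80 ± 0.27), Rasgef1c (-2.44 ± 0.12) and Trim54 (-2.33 ± 0.13) were higher in frontal cortex. Cdhr1 was uneven there, at 3.43 on young array AA against 1.00 to 1.41 on the other young arrays. Its 10 probes had age differences of -1.14 to -1.05 log2 in frontal cortex, and whether uneven dissection lies behind this was not tested. Klk8 and Nhlh1 in frontal cortex, Cyp11b1 in hippocampus and Trim54 in young hippocampus lay under the intensity minimum, so background enters the size of these differences. limma called 2897 genes, 1446 higher in hippocampus and 1451 higher in frontal cortex, and adjusted p for the genes named here was at most 0.000239 (Ttr).

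The marker lists of the regions followed the labels in part at the preset correlation, and none held otherwise: with an estimated correlation the adjusted p was 0.146 for the hippocampal, 0.536 for the neocortex, 0.65 for the choroid plexus, 0.546 for the ependyma and 0.569 for the striatum list. Of 22 measured genes of the dentate gyrus, CA1 and CA3 list, 13 were called higher in hippocampus and 5 lower (adjusted p = 3.75e-05), with Fibcd1 at 3.32, Cpne7 at 2.34 and the mineralocorticoid receptor Nr3c2 at 1.44. Of 22 neocortex genes, 10 were called higher in frontal cortex and 5 higher in hippocampus (adjusted p = 0.0459), with Mef2c at -1.86, Lamp5 at -1.75, Lmo4 at -0.90 and Pou3f1, which both lists hold, at 1.16. Choroid plexus (13 called higher, adjusted p = 3.96e-05) and ependyma (9 higher and 1 lower, adjusted p = 0.000466) were higher in hippocampus. Striatum genes (10 called lower in hippocampus, 1 higher, adjusted p = 9.95e-05) were higher in frontal cortex, with Tac1 at -2.13, Penk at -1.97, Adcy5 at -0.95 and Rasd2 at -0.89. The thalamus and septum list did not pass (adjusted p = 0.118), with Lhx9 at 1.57, Plekhg1 at 1.01, Slc17a6 at 0.95 and Ramp3 at -0.60, of which Lhx9 and Plekhg1 lay under the intensity minimum in frontal cortex.

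Myelin (3 called higher, adjusted p = 0.00148), chaperone (12 higher and 1 lower, adjusted p = 0.00435) and astrocyte genes (6 higher, adjusted p = 0.0109) were higher in hippocampus. GABAergic interneuron genes (12 called lower in hippocampus, adjusted p = 9.95e-05), which share Penk and Tac1 with the striatal list, were higher in frontal cortex. So were immediate-early (15 lower and 4 higher, adjusted p = 0.000373), endothelial (9 lower and 1 higher, adjusted p = 0.00571) and circadian clock genes (7 lower and 2 higher, adjusted p = 0.0101). With an estimated correlation none of these 7 lists held either, the smallest adjusted p being 0.241 for the circadian list.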

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

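The covariate fits with single marker lists were chosen after the marker lists had been seen, and the counts over other splits of the arrays were planned before they were run. Dixon's test at 95% picked out 25 of 708 sets of 4 arrays (3.53%), where chance picks out about 1 in 20 groups, or 35.4.

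The 97 genes called with age in frontal cortex were weighed first, because the arrays differ in neighbouring tissue. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the real one, and the highest other gave 1. As 1 of 35 is the smallest share these splits can reach, chance is unlikely for this count but not excluded. With the striatal mean as covariate the genes kept a median share of 0.992 of their difference (0.970 to 1.01 when 1 array was left out), and 52 of the 97 were called against 18 before in the same 8 arrays. With the meningeal mean the share was 0.985 (0.877 to 1.08), but 0 stayed called, since the median SE rose from 0.114 to 0.153 while the median size went from 0.560 to 0.554. The 97 genes were called in these arrays partly for a small spread within groups, which favours a share near 1 with any covariate. The meningeal mean also differs with age, at 0.42 in young and -0.21 in old frontal cortex. The shares therefore cannot decide whether striatal or meningeal tissue is a cause. These tissues, age, slides and other differences between the animals remain open.

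In hippocampus the 4 called genes and the complement and microglia list were weighed. Of 35 splits 3 gave at least 4 genes, and the highest other gave 140, so chance is not excluded for the count; that split sets Y, AB, AH and AI, the 4 arrays highest in choroid plexus markers, against the rest, which points to a structure of the samples. For the 12 lists, 12 of 35 splits gave as many and the highest other gave 27. The microglia list kept a median share of 0.993 of its difference with the choroid plexus mean as covariate (0.924 to 1.03), and 0.922 with the erythrocyte mean (0.860 to 1.00). The choroid plexus mean was 0.98 in old and 0.84 in young hippocampus, so its share could hardly move. So small a difference itself argues against uneven choroid plexus as the whole cause of that list. The erythrocyte mean differed with age, at 0.15 in old and -0.24 in young hippocampus, so its share alone cannot decide. Without old array AF, however, the median age difference was 0.076 for erythrocyte genes and 0.43 for the microglia list. That argues against blood as the whole cause, and age stays open as an untested explanation beside slides.

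Chance is unlikely for the region genes, since 1 of 100 regroupings, the real one, gave 2897 and the highest other gave 1. It is not excluded for list counts: 15 of 35 splits gave at least the 7 cortical lists (highest other 12) and 26 of 100 regroupings at least the 12 region lists (highest other 18). For the difference of age effects the count was 0, which all 100 regroupings reach, and the highest other was 68.

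List means far from the other 3 arrays of their group were those of myelin (0.41 log2) and striatum (1.73) on old frontal cortex array AG, synaptic genes (-0.27) and GABA receptors (-0.23) on old hippocampus array AI, and T and B cell genes (1.11) on young frontal cortex array AB. On AG the striatal mean of the other 3 arrays lay between 0.18 and 0.41, and Adcy5, a striatal marker, stood at 2.53 against 1.29 to 1.40.

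Single genes were far from their group on these arrays, in log2 relative to the 75th percentile. Young hippocampus array Y stood apart in A2m (1.06), Vtn (0.89), Igf1 (-0.24) and Tspy26 (-2.99), and array AA in Clmp (-1.60), Heatr8 (-1.55) and Npff (-1.83). Arc was low on young hippocampus array AB (1.22), Klf1 high on old hippocampus array AF (-2.40), and Nrxn3 low on old hippocampus array AI (2.08). In young frontal cortex A2m (-1.82) and Cabp7 (-1.10) were low on array Y, Cdhr1 (3.43) and Igf1 (-0.27) high on array AA, and Rpl4 (4.33) low on array AB. In old frontal cortex Cyp11b1 (-0.15) and Shisa3 (-4.13) were low on array AG, Cabp7 (-0.98) on array AF and Ucma (0.039) on array AH.

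Age effects differed between the regions in 11 lists by camera on the interaction, hippocampus minus frontal cortex, and no list held with an estimated correlation (smallest adjusted p = 0.605). Median differences were 0.29 log2 for complement and microglia, 0.38 for MHC class II, 0.13 for MHC class I, 0.18 for astrocyte, -0.22 for myelin, 0.18 for immediate-early, 0.057 for oxidative phosphorylation, 0.13 for antioxidant, 0.072 for chaperone, 0.13 for lysosome, and 0.47 for pericyte and meninges genes.

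Of 5909 kept probes without a listed gene, which enter no comparison, 58 were called with age in frontal cortex (48 higher, 10 lower) and 1098 between regions (476 higher in hippocampus, 622 lower). In hippocampus limma called 0 of them with age.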

How the results depend on the processing

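Fits with single marker lists as covariates, without codes AF and AG, and over both regions were added after the data had been seen. The 3 other scalings left hippocampus at 4 genes and frontal cortex at 89 to 92. The deposited columns already share their quartiles, so these scalings could change little and do not test the authors' normalization. No called gene named in the text changed sign under any alternative, which selection in the same arrays makes likely. A value without a call that changed sign is counted as moved. Hippocampus genes, 4 in the text, numbered 8 with array weights, 1 with only the 8 arrays of the region, 1 with the first component of the dissection markers, 0 with the striatum mean, 1 with the choroid plexus mean, 6 with the meningeal mean (3 of the 4 among them), 1 with the erythrocyte mean, and 20 without AF and AG. Leaving out 1 array gave 1 to 7. The 12 hippocampal lists became 4 with the stricter filter, all higher, and 1 with an estimated correlation, and 7 to 17 with 1 array left out. Frontal cortex genes, 97 in the text, numbered 47 without a filter, where more genes are tested, 29 with only the 8 arrays of the region (18 of them among the 97), where fewer arrays set the spread, and 45 with at least a 1.5-fold change. They numbered 55 with the dissection component, 141 with the striatum mean (105 higher, 36 lower), 8 with the choroid plexus mean, 3 with the meningeal mean, 36 with the erythrocyte mean and 2 without AF and AG, and 4 to 739 with 1 array left out. The covariate fits use 8 arrays, so their baselines are 1 gene in hippocampus and 29 in frontal cortex. The 7 frontal cortex lists became 0 with an estimated correlation, 11 without AF and AG, and 4 to 9 with 1 array left out. The interaction stayed at 0 to 1 genes. Region genes fell to 789 with the fold minimum and region lists to 0 with an estimated correlation. The correlation of age effects was 0.408 without AF and AG. The 9 lists over both regions became 0 with an estimated correlation, fitted without a block. The both-region count of 299 became 18 to 1199 with 1 title code left out. Where no cause is given, the cause was not tested. With the title code as a random block the counts were 4, 95, 0 and 3005 genes, and as a fixed effect 2896 region genes. Of the 8 code pairs 3 had an r over 0.1 (-0.171 to 0.282), so the codes were not used to pair arrays. Of the values of single named genes, 2905 were the same with 1 array left out, 120 lost a call, 33 gained one and 14 moved. Under all other alternatives, title codes left out among them, these were 2387, 180, 27 and 12. With 1 array left out, called region and both-region genes lost no call, and uncalled genes had none to lose. All 120 losses therefore fell on genes called with age within a region. Another background correction was not run, because the columns that hold it match no sample. Dark corners at 5.03 log2 against a minimum of 6.49 for kept genes limit what can be said of dim genes.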

Other observations

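Both tests here, age averaged over the regions and the comparison of title codes, were chosen after the data had been seen. The splits of the title codes count calls of the first test, so they too were set after that, though before they were run.

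Old and young rats were compared gene by gene, averaged over both regions, with the title code as a random block. The block used 1 correlation for all genes, 0.0506, so arrays of the same code counted almost as independent replicates. If a code is an animal, p may be too small for genes whose arrays share more than this. The count of 299 genes may then be too high. C3 was higher by 1.33 ± 0.10 log2 (adjusted p = 8.40e-06), S100a4 by 1.09 (adjusted p = 0.000135), Lsp1 by 0.75 (adjusted p = 0.00106), Pla2g7 by 0.59 (adjusted p = 0.0011) and Gpnmb by 0.61 (adjusted p = 0.00253). Mt2A was higher by 1.03, Trem2 by 0.44 and Tyrobp by 0.42, and Dusp1 (-0.55), St8sia5 (-0.56) and Foxo6 (-0.50) were lower. limma called 299 genes, 186 higher and 113 lower. Of 35 splits of the title codes 1 gave as many, the real one, and the highest other gave 48. As 1 of 35 is the smallest share these splits can reach, chance is unlikely for this count but not excluded. The complement and microglia list passed camera with 10 of 28 members called higher (adjusted p = 4.37e-14), and the immediate-early list with 4 of 26 called lower (adjusted p = 0.000512). Both calls were lost with an estimated correlation, fitted without the block (adjusted p = 0.506 and 0.812).

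The size of that count rests on single arrays. It was 1033 without old frontal cortex array AI and 170 without AG, and 460, 40 and 538 without old hippocampus arrays AF, AH and AI. Without young frontal cortex arrays AA, AB, Y and Z it was 48, 35, 162 and 103, and without young hippocampus arrays AA, AB, Y and Z 115, 75, 137 and 88. C3, S100a4, Lsp1, Gpnmb, Dusp1 and St8sia5 were called in all 16 of these fits. With a code left out in both regions, Trem2 lost its call without AB, Tyrobp without AB or Z, and Foxo6 without AA, AB, Y or Z.

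Erythrocyte markers were highest under code AF in both regions and low under AG (-0.51 in hippocampus, -0.70 in frontal cortex). Over the 8 codes the list means of the regions correlated with a Pearson r of 0.934 and a Spearman rho of 0.929 (exact permutation within ages, two-sided, p = 0.00347 for each), and r was 0.841 without AF and Z. Adjusted over the 40 lists tested this way, p was 0.0694. Blood markers do not stand alone in this, as the glucocorticoid response list had an r of 0.978 (adjusted p = 0.0694). The complement and microglia list had an r of 0.913 (adjusted p = 0.347), but its median was higher with age in both regions. Each r spans both ages, so a shared age difference raises it, and only the permutation p sets age aside. A candidate explanation is that arrays with the same code come from the same animal, whose blood content and other traits they would share. Over all genes, 3 of the 8 codes (AF, AI and AA) matched their own code best and 5 did not, which does not settle whether a code is an animal.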
